A study of Homo sapiens with 6 samples.

How the data were processed

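Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in nuclei of Jurkat cells, an established human T-cell leukaemia line. Per the labels, 3 libraries were kept at normal gravity (NG 1 to NG 3) and 3 were made under simulated microgravity (SMG 1 to SMG 3). Nuclei from 50000 cells per library were prepared with a 3 min lysis and tagged with transposase for 30 min at 37 °C. In the microgravity group, per the labels, the nuclei, not intact cells, sat in a random positioning machine that turned at 30 degrees per second for 30 min. Whether the rotation and the transposition ran at the same time is not given in the sources used here.

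The authors deposited 1 peak list per library, with 10 columns and no header, in the narrowPeak layout that MACS2 writes. Per the submitters' processing notes, the tools were FastQC, BWA, Bowtie, SAMtools and MACS2 and the genome build was hg38. Their versions, their settings, the handling of duplicate reads and any shift of reads for the transposase are not given in the sources used here. The deposited score of a peak, an integer, equalled 10 times its −log10 q-value for 99.955 to 100% of peaks in each library. The deposited fold enrichment is the height of the peak summit over the local background, a linear ratio. The deposited −log10 p-value and −log10 q-value come from the authors' peak caller, and the largest q-value in a list was 0.0474 to 0.0496. Peaks were called in each library separately, as the peak names in the deposited lists show. Names in the list of SMG 3 carry the word "normalized" and those of the other 5 libraries do not, and the meaning of the word is not given in the sources used here.

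The lists hold no read counts, so depth was estimated from the deposited values. With the formulas of MACS2, the fold enrichment and the −log10 p-value together fix a whole-number summit pileup and a local background for each peak. Over 99.9% of peaks in each library were solved in this way within 0.001 of the deposited −log10 p-value (99.947 to 99.966%). The lowest background in a library was taken as its genome-wide background, a measure of depth that rests on these formulas. It was a pileup of 1.17, 1.77 and 1.42 fragments per base in NG 1, NG 2 and NG 3, and 1.59, 1.73 and 1.59 in SMG 1, SMG 2 and SMG 3. In the main comparisons scores, folds and heights were used only to rank peaks within their own library, as percentiles by −log10 q-value, since they move with depth. The stricter common score and the thinning of summit pileups, both described below, set them against other libraries.

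Peaks of the 6 libraries were merged into union regions wherever they overlapped by at least 1 bp, and a library held a region if 1 of its peaks overlapped it. Similarity of 2 libraries was the Jaccard index, the shared bases over the bases covered by either. Gene positions came from a RefSeq table of the same human assembly, with 59792 genes, of which 20033 protein-coding genes on 24 chromosomes were used. All 561 entries of the gene lists were matched to it, 1 of them by an older symbol. The table gives no strand and no transcript starts, so promoters could not be told from the far ends of genes. The planned promoter window was replaced by a gene-end window of 1 kb to each side of both ends of a gene. A promoter farther inside a gene was not covered, so a gene without a gene-end peak may still have an open promoter. A peak was classed by its centre as at a gene end, within a gene (protein-coding or long noncoding, outside gene-end windows) or intergenic. A gene had a gene-end peak in a library if any peak overlapped 1 of its windows. The planned search for transcription factor motifs was not run, since no genome sequence was used here.

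Group means were compared with exact permutation tests, two-sided, over the 10 splits of 6 libraries into 3 and 3. The smallest p such a test allows is 0.1, so no group difference could pass 0.05 in this test. The labels do not say that the libraries of a group came from separate cultures, so each p measures only the spread between these libraries, which may be technical. Counts of regions or genes found in every library of 1 group and none of the other were set beside the counts for all 20 sets of 3 libraries. Location and gene lists of group-only regions were compared with those of the other regions held by exactly 3 libraries, by Fisher's exact test, two-sided. Regions went to the nearest protein-coding gene end within 50 kb. Adjusted p-values are Benjamini-Hochberg values. The 29 gene lists, the tests of the group comparisons, their alternatives and the rule for naming genes were fixed before the data were examined, apart from the change of window and the tests and alternatives stated as chosen later. The rule named, per direction, the 12 genes with the highest mean score percentile of their best gene-end peak, the 6 group-only regions with the highest mean percentile, every list member with a peak in all libraries of 1 group and none of the other, up to 3 of the strongest members per list with a peak in all 6 libraries, and members without a peak in any library for the lists of other cell types and of genes deleted in Jurkat cells. Genes named outside this rule are stated to be chosen after their values were seen.

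The counting was tested on simulated data with 69562 regions and 200 planted SMG-only regions. With detection of a planted region in every SMG library 99% of the 200 were recovered. With detection in each library at rates of 0.9 and 0.7, 69% and 37.5% were recovered, beside 72.9% and 34.3% from the rates alone. In all, these simulations counted 466, 410 and 370 SMG-only regions, against 198, 138 and 75 planted regions recovered. They also counted 258, 265 and 277 NG-only regions, where none had been planted, so group-only regions also arise without a group effect. Overlaps were checked against bedtools 2.31.1, with 0 differences. Alternatives were an equal number of peaks per library (the top 37782), a stricter common score (−log10 q-value of at least 8.27, the median of all peaks), autosomes alone, other overlap rules, gene-end windows of 3 kb and 500 bp, another background for the enrichment tests, a pairing by replicate number and leaving out each library in turn. Leaving out NG 1 and SMG 3 together was chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.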

Results

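Open chromatin was mapped in Jurkat nuclei to ask whether their accessible genome differed between normal gravity and simulated microgravity. Per the labels nuclei, not intact cells, were turned, so these data do not test a response of intact T cells. The 3 libraries at normal gravity held 37782, 43713 and 40601 peaks, and the 3 libraries under simulated microgravity held 42222, 42399 and 39624. Merging gave 69562 union regions, of which 24103 (34.6%) were held by all 6 libraries and 24310 (34.9%) by a single library. Regions held by all 6 libraries had a median score percentile of 70.3 within their libraries and 32.5% of them lay at a gene end. Regions held by 1 library had a median percentile of 12.9, with 6.39% at a gene end.

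**Figure D1:**
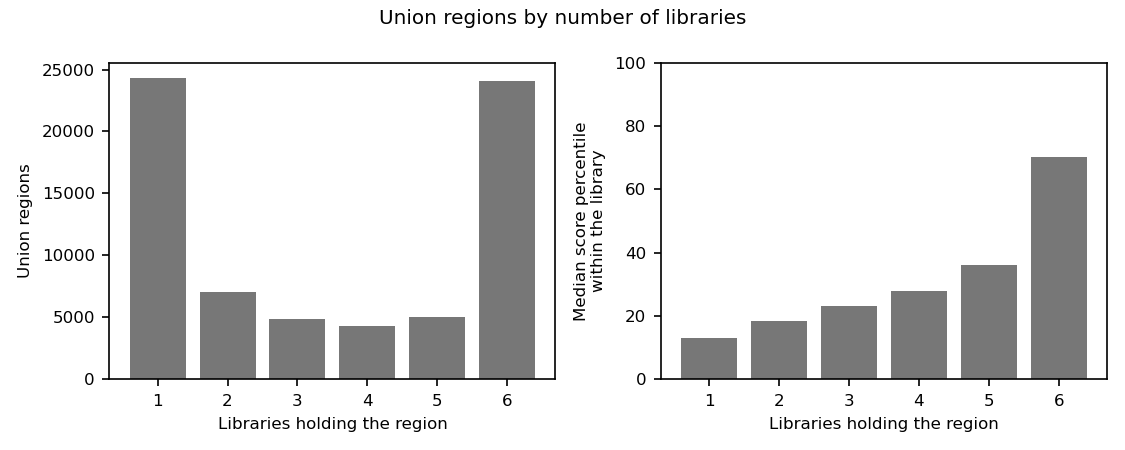
Number of union regions (left) and their median score percentile within the library (right) against the number of libraries that hold a region. The 24103 regions held by all 6 libraries had a median percentile of 70.3, against 12.9 for the 24310 regions held by 1 library.

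Most genes of T cell identity had a gene-end peak in both groups. CD3E, a chain of the T-cell receptor complex, CD2, an adhesion receptor of T cells, and CD8A, a co-receptor, had gene-end peaks in all 6 libraries, at mean score percentiles of 96.7, 93.0 and 89.3. CD4, also a co-receptor and chosen after its values were seen, had one in 1 NG and 1 SMG library, at a mean percentile of 2.44. A gene-end peak does not show that a gene is expressed. Of 26 T cell identity genes, 19 had a gene-end peak in all 6 libraries and 3 in none, which were CD5, TCF7 and PTPRC. Of 14 regulators of T-cell leukaemia, 7 had one in all 6 libraries, among them TCF3, LMO1 and MYC, and 5 in none, namely TAL1, GATA3, LMO2, ETS1 and ERG. The absent genes of these lists were chosen after their values were seen. Among the absent genes, ETS1 was the nearest gene of 7 regions held by all 6 libraries, PTPRC of 4 and CD5 of 3. TCF7 and GATA3 were the nearest gene of 2 each, TAL1 and LMO2 of 1 each and ERG of 0. A promoter inside a gene and outside the windows at its ends would be missed, so absence here does not show a closed promoter. Whether the base composition of these gene ends bears on their absence was not tested, as no genome sequence was used here. CDKN2A and CDKN2B, cell cycle inhibitors listed as deleted in Jurkat cells, had no peak in any library. They lay in a stretch of 2324 kb of chromosome 9 (21119735 to 23443824, hg38) without a peak in any of the 6 libraries.

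The first comparison asked whether simulated microgravity changed how much chromatin was open and where in relation to genes. Peaks at gene ends made up 24.2% ± 0.569 (SD, n = 3) of the peaks at normal gravity and 24.3% ± 0.703 (SD, n = 3) under simulated microgravity (exact permutation p = 0.9, two-sided). Peaks within genes made up 45.2% ± 0.297 and 45.7% ± 0.503 (exact p = 0.3), and intergenic peaks 28.1% ± 0.442 and 27.4% ± 1.36 (exact p = 0.5). Among 20033 protein-coding genes, 10662 ± 454 had a gene-end peak at normal gravity and 10729 ± 248 under simulated microgravity (SD, n = 3 each, exact p = 0.9). Gene ends of 9331 genes were open in all 6 libraries and those of 7962 genes in none.

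The number of peaks was 40699 ± 2967 at normal gravity and 41415 ± 1554 under simulated microgravity (SD, n = 3 each, exact permutation p = 0.7, two-sided). Peaks covered 21.2 ± 2.94 Mb and 22.4 ± 0.826 Mb of the genome (exact p = 0.6), with a median width of 460 ± 31.9 bp and 475 ± 13.1 bp (exact p = 0.6). Each of these differences was smaller than the SD of at least 1 group, and the exact permutation test of 3 against 3 libraries allows no p below 0.1. Without NG 1 the differences in number, cover and width changed sign (−742 peaks, −0.312 Mb and −3.83 bp), and without SMG 3 the intergenic difference did (0.0506 percentage points). The difference in gene-end share changed sign without NG 2 (−0.230 percentage points) or SMG 3 (−0.305), with the narrower 500 bp window (−0.254) and at the stricter score (−1.89), where the intergenic difference was 0.343. Across the 6 libraries the number of peaks followed the recovered background, with a Pearson r of 0.887 (exact permutation p = 0.0167, two-sided) and a Spearman rho of 0.829 (exact permutation p = 0.0583). This was the 1 relation computed, and without NG 1 and NG 2, the samples farthest from the median, r was 0.523 over 4 libraries, so that the relation rests on those samples.

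**Figure D2:**
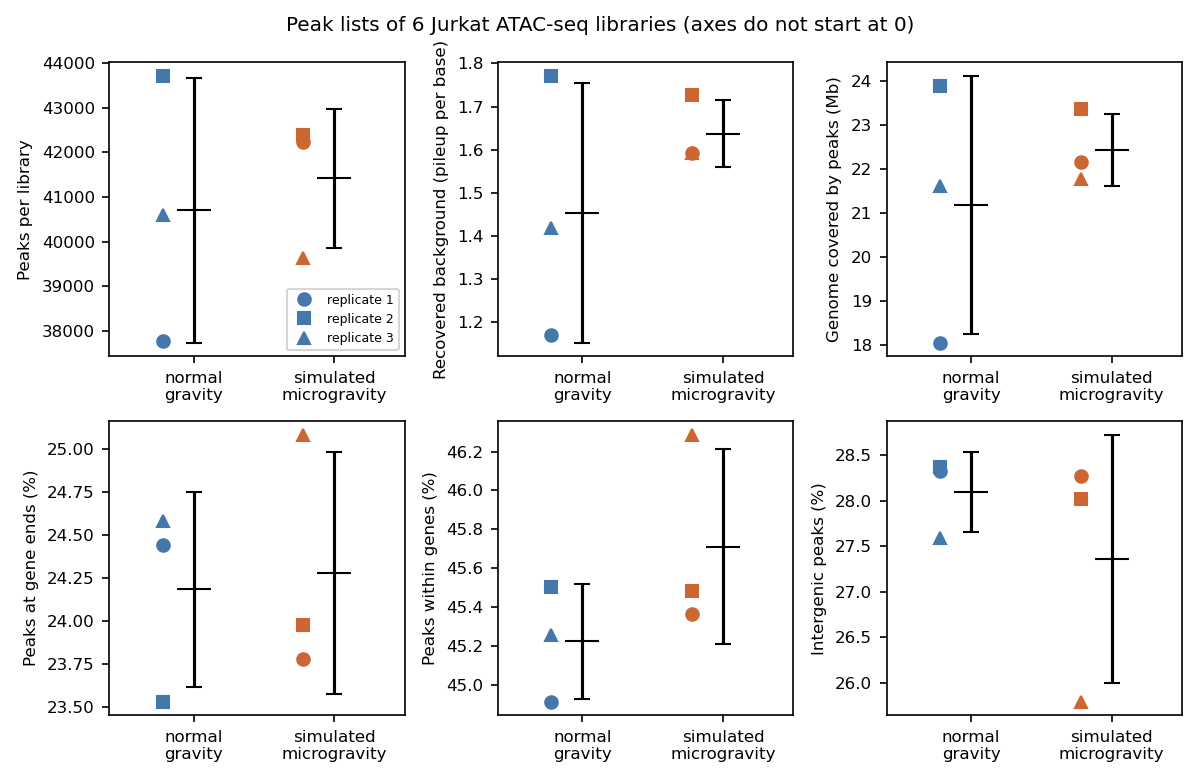
Values of each library (points, shape by replicate number) by group, with the group mean and SD (bars, n = 3): number of peaks, recovered background, genome covered in Mb, and percent of peaks at gene ends, within genes and intergenic; the vertical axes do not start at 0. NG 1 is lowest in peaks (37782) and cover (18.1 Mb), and SMG 3 is lowest in intergenic peaks (25.8%).

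The second comparison asked which regions had a called peak in 1 condition alone. Signal under the calling threshold could not be seen, so a missing peak does not show closed chromatin. A peak in every SMG library and no NG library was found in 286 regions, or 0.411% of the union, and the reverse in 181 regions, or 0.260%. The 6 strongest SMG-only regions lay within the span of a protein-coding or long noncoding gene. Distances run to the nearest end of a protein-coding gene, so a region may lie inside the gene named. On chromosome 6 (6494208 to 6494537) the nearest gene end was that of LY86, at 94.3 kb. On chromosome 2 (74037347 to 74037582) it was that of TET3, which encodes an enzyme that oxidises methylated cytosine, at 53.8 kb. The distances to LY86 and TET3 exceed the limit used to assign regions to genes in the list tests. For the region on chromosome 6 (89372074 to 89372374) it was that of RRAGD, a GTPase of nutrient sensing, at 7.61 kb. The others were near PGAP6 on chromosome 16 (380150 to 380425), SEPTIN2 on chromosome 2 (241352259 to 241352796) and ANXA2R on chromosome 5 (43038012 to 43038219). The strongest NG-only region was intergenic, on chromosome Y (56706942 to 56707183), at a mean percentile of 62.6. Its nearest protein-coding gene end, that of CDY1, lay 31081.6 kb away. Peaks in repeated sequence were not filtered out here, and whether read mapping bears on this region was not tested. Next came the shared gene end of ANKRD13A and GIT2 on chromosome 12 (109999002 to 109999490), a region near MRPS18A, a mitochondrial ribosomal protein, on chromosome 6 (43668112 to 43668581), and the gene end of SNX32 on chromosome 11 (65833729 to 65834059). The others lay near PLPPR5 on chromosome 1 (98897501 to 98897958) and at a gene end of LOC124903130 on chromosome 13 (21377190 to 21377789).

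These group-only regions were weak peaks. The SMG-only regions had a median score percentile of 25.1 and the NG-only regions 21.2, close to the 22.995 of all 4824 regions held by exactly 3 libraries. Over the 20 sets of 3 libraries the count ran from 102 (NG 1, NG 3 and SMG 3) to 537 (NG 2, SMG 1 and SMG 2), with a median of 212.5, and the SMG set ranked 6 and the NG set 12. A single region with 3 libraries against 0 has a Fisher's exact p of 0.1, two-sided, so no region passes alone. At the stricter score, which kept the fewest peaks in NG 1 (15496), 149 SMG-only and 47 NG-only regions were counted. Without NG 1 the order turned, with 421 SMG-only and 831 NG-only regions, but an NG-only region then needed a peak in fewer libraries than an SMG-only region.

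**Figure D3:**
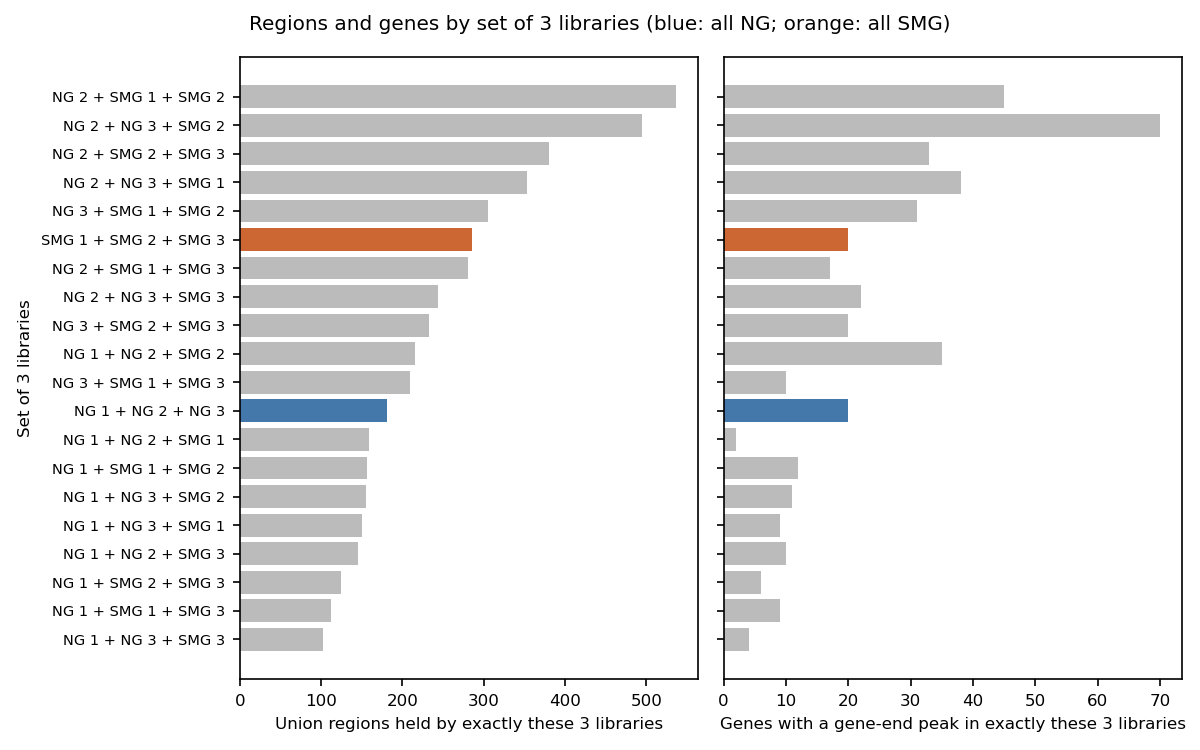
Number of union regions held by exactly 3 libraries (left) and of protein-coding genes with a gene-end peak in exactly 3 libraries (right), for each of the 20 sets of 3 libraries. The 3 SMG libraries (orange, 286 regions and 20 genes) and the 3 NG libraries (blue, 181 regions and 20 genes) lie inside the range of the mixed sets (102 to 537 regions).

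The peak sets of the same group were no closer to each other than those of different groups. The Jaccard index of pairs of libraries ran from 0.516 (NG 1 and SMG 3) to 0.611 (NG 2 and SMG 2). Its mean was 0.5665 within groups and 0.5672 between groups, a difference of −0.000677 (exact permutation p = 0.4, one-sided, over 10 splits). Without NG 2 or NG 3 the difference was above 0 (0.0133 and 0.00714).

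The third comparison asked which genes had a called peak at a gene end in 1 condition alone. A gene-end peak in all SMG and no NG libraries was found at 20 protein-coding genes and the reverse at 20 others. The strongest 12 SMG-only genes, in order of mean percentile, began with ZNF16, a zinc finger protein (chromosome 8, 144950551 to 144951064), and ANKLE1 (chromosome 19, 17282522 to 17283011). BTBD7 and UNC79, which shared a peak between them (chromosome 14, 93332940 to 93333511), came next. RAET1G, a ligand of the NKG2D receptor of killer cells (chromosome 6, 149922854 to 149923308), and KISS1, the kisspeptin precursor (chromosome 1, 204190304 to 204190868), followed. After them came TGFB1I1, an adaptor at focal adhesions (chromosome 16, 31476525 to 31477242), and KIF21B, a kinesin motor (chromosome 1, 200969980 to 200970424). APPL2, an adaptor of endosomes (chromosome 12, 105236128 to 105236453), and ARRDC5 (chromosome 19, 4916507 to 4917013) were next. CAPZB, a subunit of the actin capping protein, and ZNF730 (chromosome 19, 23075159 to 23075699) completed the 12. No theme was tested for these genes as a set.

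The strongest 12 NG-only genes included GIT2, a GTPase-activating protein of Arf proteins, which shared its peak with ANKRD13A, CHST12, a chondroitin sulfotransferase (chromosome 7, 2402944 to 2403430), ISYNA1, the inositol phosphate synthase (chromosome 19, 18436874 to 18437381), and MCMBP, a binding partner of the replicative helicase (chromosome 10, 119872828 to 119873520). RERG, a Ras-like GTPase, and LOC124902886 shared a peak (chromosome 12, 15220949 to 15221633). DLX6, a homeobox gene (chromosome 7, best peak 97005149 to 97005348, with a separate NG-only region at 97006076 to 97006413), CCDC187 (chromosome 9, 136306247 to 136306932), C10orf120 (chromosome 10, 122696691 to 122697250), LOC124902693 and LOC124903130 were the others. CD81, a tetraspanin, JAK3, a kinase of cytokine receptors, and AKT1, a kinase of growth signalling, were among the 8 weaker NG-only genes and were chosen after their values were seen, with mean percentiles of 21.9, 19.4 and 14.6. A peak of the other group overlapped the best gene-end peak or lay within 1 kb of it, outside the window, at 2 SMG-only genes, AVPR2, where it overlapped, and RUFY3, at 669 bp, and 2 NG-only genes, AKT1, where it overlapped, and MCMBP, at 450 bp; RUFY3 and AVPR2 were chosen after their values were seen.

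The best gene-end peaks of the SMG-only genes had a median score percentile of 28.8 and those of the NG-only genes 29.8, against 81.0 at genes open in all 6 libraries. The counts for the 20 sets of 3 libraries ran from 2 to 70, with a median of 18.5, and both groups ranked 8. At the stricter score 24 SMG-only and 7 NG-only genes were counted, and 0 of them were among the genes counted without it. This was fixed in advance, since each gene counted without it had a library whose best gene-end peak fell below that score. Not all of the genes rested on a group-only region: 15 of the 20 SMG-only and 18 of the 20 NG-only genes did, and CAPZB did not.

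The fourth comparison asked whether gene groups chosen for T cells and for gravity changed together. Of 556 genes on the 29 lists, 327 had a gene-end peak in all 6 libraries and 135 in none, and 0 had the peak in all libraries of 1 group and none of the other. Of 28 immediate early and activation genes, 14 had a gene-end peak in all 6 libraries, the strongest at EGR1, FOS and JUN, transcription factors induced within minutes of stimulation (mean percentiles of 98.6, 87.8 and 98.5), and 9 had none in any, among them IFNG and TNF, chosen after their values were seen. Their list had 60.7% ± 3.57 (SD, n = 3) of its 28 members open at normal gravity and 63.1% ± 4.12 under simulated microgravity (exact permutation p = 0.7, two-sided). T cell identity genes stood at 80.8% ± 3.85 and 79.5% ± 2.22 (exact p = 1), leukaemic regulators at 59.5% ± 4.12 and 64.3% ± 0 (exact p = 0.4), checkpoint receptors at 30.0% ± 10.0 and 36.7% ± 5.77 (exact p = 0.7), and regulators of helper and regulatory T cells at 54.5% ± 4.55 and 54.5% ± 0 (exact p = 1). The NF-kappaB pathway, with NFKBIB, BIRC3 and BCL10 open in all 6 libraries, stood at 86.0% ± 3.04 and 87.7% ± 3.04, and MAPK signalling, with MAP2K1, SOS1 and DUSP6, at 93.1% ± 8.67 and 94.4% ± 2.41 (exact p = 1 for both).

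Genes of the cytoskeleton and of mechanosensing, chosen as the groups closest to a mechanical stimulus, differed between conditions by less than the SD of a group. Since nuclei and not intact cells were turned, these shares do not test mechanosensing by whole cells. Cytoskeletal genes, with VCL, RHOA and TUBA1A open in all 6 libraries, stood at 73.8% ± 2.06 at normal gravity and 75.0% ± 7.14 under simulated microgravity (SD, n = 3 each, exact permutation p = 1, two-sided). Integrins and adhesion genes, with ITGA4, ICAM2 and ICAM3, stood at 74.1% ± 3.21 and 75.9% ± 6.42, and mechanosensing and Hippo genes, with STK4, MOB1A and EMD, at 44.0% ± 10.3 and 44.0% ± 5.46 (exact p = 1 for both). PIEZO1 and PIEZO2, mechanically gated ion channels, had no gene-end peak in any library and were chosen after their values were seen.

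Stress, growth and energy genes were mostly open in both conditions. Apoptosis genes, with BCL2L1, APAF1 and CYCS, stood at 83.3% ± 4.17 at normal gravity and 81.9% ± 2.41 under simulated microgravity, and heat shock and unfolded protein genes, with HSPD1, HSPE1 and EIF2AK3, at 77.3% ± 0 and 78.8% ± 2.62 (SD, n = 3 each, exact permutation p = 1 for both, two-sided). The p53 and DNA damage list, with MDM2, ATM and PRKDC, stood at 95.5% in each of the 6 libraries. Cell cycle genes, with CDK2, CDK4 and MCM3, stood at 91.0% ± 5.88 and 93.6% ± 4.44 (exact p = 0.7), oxidative stress genes, with SOD2, CAT and PRDX3, at 86.0% ± 6.08 and 84.2% ± 0 (exact p = 1), and chromatin regulators, with SMARCA2, HDAC2 and SMC3, at 90.3% ± 0 and 91.4% ± 1.86 (exact p = 1). Mitochondrial respiration, with ATP5F1B, ATP5MC1 and TFAM, stood at 92.1% ± 5.50 and 93.7% ± 2.75, and ribosomal proteins, with RPL5, RPL27 and RPS14, at 95.5% ± 0 and 93.9% ± 2.62 (exact p = 1 for both).

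Interferon response genes, with STAT2 and MX2 open throughout, stood at 69.8% ± 13.7 at normal gravity and 81.0% ± 4.76 under simulated microgravity (SD, n = 3 each, exact permutation p = 0.4, two-sided), with NG 2 as high as the highest SMG library (85.7%). Chemokine and cytokine receptors, with IL6ST, IFNGR1 and IFNAR1, stood at 58.3% ± 4.17 and 66.7% ± 4.17 (exact p = 0.2), and glycolysis genes, with PGK1, LDHB and PDK1, at 84.1% ± 2.75 and 79.4% ± 2.75 (exact p = 0.3). Set against the share of all protein-coding genes in the same library, the SMG minus NG difference was 7.997 percentage points for receptors and −5.10 for glycolysis genes, with no overlap of the groups (exact p = 0.1, adjusted p = 0.916 for both). Of 29 lists, 0 were without overlap before this step and 2 after it, where chance alone gives 10%. The smallest adjusted p over lists was 1 before it and 0.916 after it. Single genes that differed by 2 or more libraries between groups were 7 with more SMG libraries, among them NFKBIA, IL12RB1 and SELPLG, and 4 with more NG libraries, ROCK2, SRXN1, IL7R and TPI1, chosen after their values were seen. With the 3 kb window 2 lists were without overlap before any comparison with all genes.

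**Figure D4:**
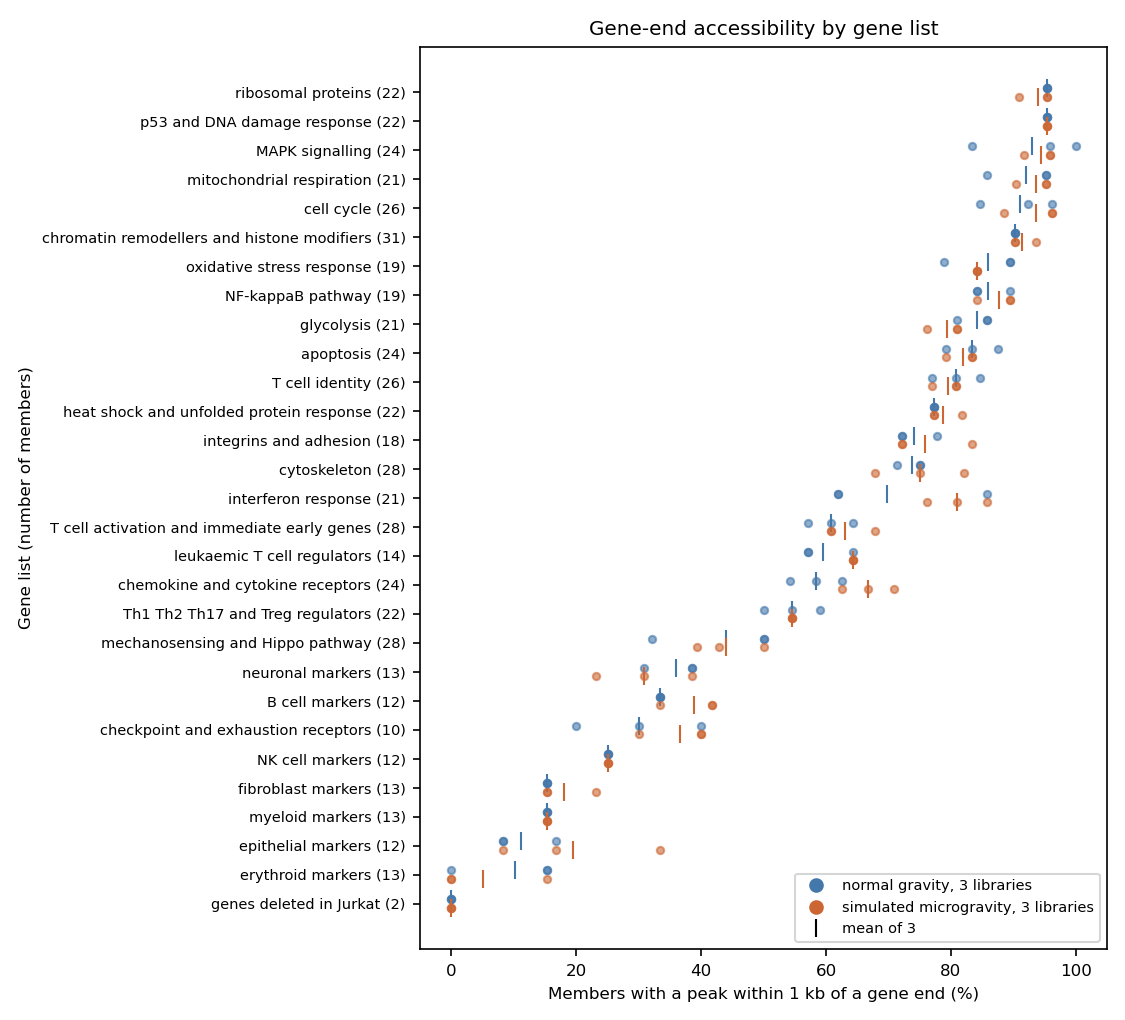
Percent of the members of each of 29 gene lists with a peak within 1 kb of a gene end, for 3 libraries at normal gravity (blue) and 3 under simulated microgravity (orange), with points for libraries and ticks for group means. The groups overlap in each list; T cell identity genes lie at 76.9 to 84.6% and myeloid markers at 15.4% in all 6 libraries.

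Most marker genes of other cell types were without a gene-end peak in both conditions. Myeloid markers stood at 15.4% and NK cell markers at 25% in each library. CEBPE and CD68 of the myeloid list and GNLY, NKG7 and PRF1 of the NK list had a gene-end peak in all 6 libraries, GNLY at a mean percentile of 81.6, while CD14, LYZ and CSF1R, and NCAM1 and KLRD1, had none in any. Erythroid markers stood at 10.3% ± 8.88 at normal gravity and 5.13% ± 8.88 under simulated microgravity, epithelial markers at 11.1% ± 4.81 and 19.4% ± 12.7, fibroblast markers at 15.4% ± 0 and 17.9% ± 4.44, neuronal markers at 35.9% ± 4.44 and 30.8% ± 7.69, and B cell markers at 33.3% ± 0 and 38.9% ± 4.81 (SD, n = 3 each, exact permutation p from 0.4 to 1, two-sided). COL1A1 and FBN1 of the fibroblast list, SNAP25, SYT1 and GAD2 of the neuronal list and EBF1, BLK and CR2 of the B cell list had one in all 6 libraries, at mean percentiles from 36.3 (BLK) to 68.4 (SYT1). HBB, EPCAM, COL3A1 and RBFOX3 had no gene-end peak in any library.

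The last comparison asked where group-only regions lay and which genes they were near. SMG-only regions were intergenic in 28.0% of cases against 34.4% of the other regions held by exactly 3 libraries (odds ratio 0.741, Fisher's exact p = 0.0285, two-sided, adjusted p = 0.171) and within genes in 56.3% against 50.9% (odds ratio 1.24, adjusted p = 0.263). They lay at gene ends in 10.5% against 11.3% (odds ratio 0.921, Fisher's exact test, adjusted p = 0.772). NG-only regions lay at gene ends in 14.4% against 11.1% (odds ratio 1.34, Fisher's exact test, adjusted p = 0.372), within genes in 48.6% against 51.4% (odds ratio 0.896, adjusted p = 0.595) and between genes in 36.5% against 33.9% (odds ratio 1.12, adjusted p = 0.595). None of these passed 0.05 after adjustment. Of 58 tests of gene lists among group-only regions, by Fisher's exact test, 0 passed an adjusted p of 0.05, and 1 passed 0.05 unadjusted, glycolysis genes among SMG-only regions (2 of the 271 regions on the 24 chromosomes against 3 of 4385, adjusted p = 1). With all other union regions as background, the gene-end odds ratio of SMG-only regions was 0.573 and the within-gene ratio 1.41, each with an adjusted p of 0.0130, a background that also holds the strong regions of all 6 libraries. Regions are not independent replicates, and these tests compare regions of these 6 libraries.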

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

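The tests of depth, of library yield, of the number of peaks of each library, of simulated microgravity, of the word "normalized" and of the splits were chosen only after the results were seen, while the tests of the peak number and weak peaks of SMG 3 were set before their results were seen.

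Peaks on contigs outside the 24 chromosomes and the mitochondrial genome entered no comparison of genes, and were more numerous on average in the SMG libraries (1087.67) than in the NG libraries (1012.33), with an exact permutation p of 0.5, two-sided. Of the 286 SMG-only regions 15 lay outside the 24 chromosomes, and 1 of the 181 NG-only regions did, beside 1718 of all 69562 union regions. These small counts were not tested. Alternate contigs of chromosome 6 held 251 peaks in SMG 3 and 118 to 204 in the other 5 libraries.

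NG 1 lacked 2136 regions that the other 5 libraries all held, while the other libraries lacked 278 to 1115 such regions. Lower depth of NG 1 was tested by thinning the summit pileups of each other library to the background of NG 1 and counting what it then lacked of the regions held by the remaining 4. Thinning closed a median of 20.1% of the gap to NG 1 (9.07% with NG 3 to 35.7% with SMG 3), as far as the recovered background measures depth. Each peak was thinned at its summit alone, and whether it would still span the smallest width, 200 bp in each library, was not tested. The share closed may thus be too low, and lower depth may account for a part or the whole of the gap. A lower share of reads in peaks was not tested. No biological explanation was tested, since the other libraries of its group did not share the pattern.

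SMG-only regions outnumbered NG-only regions (286 against 181), a direction that turned without NG 1 (421 against 831). In that setting an NG-only region needed a peak in fewer libraries than an SMG-only region, so these counts were not on equal terms. A model with 1 term for the yield of each library, fitted to the other 18 sets of 3 libraries, predicted 270 and 170 regions, a ratio of 1.59 against the observed 1.58, so the excess may reflect properties of single libraries. The number of peaks alone does not account for the excess, since at an equal number of peaks the ratio was 1.48 (239 against 162), where library terms predicted 1.45. At the stricter score the ratio was 3.17 (149 against 47), where library terms predicted 3.30. That score kept 15496 peaks of NG 1 and 20095 to 23113 of the other libraries, so the ratio of 3.17 does not speak against the number of peaks. An effect of simulated microgravity that opened some regions and closed others would raise both counts above the model. Together they stood at 1.06 times the prediction, while another split reached 1.12, so that with 10 splits such an effect and chance cannot be told apart. An effect in 1 direction was not tested separately. A change in the yield of all SMG libraries would be taken up by the library terms, so the model cannot tell it from properties of single libraries. Of the 10 splits, 5 gave as many group-only regions as the real 467 (highest other 639), 7 as many genes as the real 40 (highest other 79) and 4 as large a Jaccard difference as the real −0.000677 (highest other 0.00458), and 10 splits are too few for a share under 0.05.

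SMG 3 had the lowest intergenic share of peaks, 25.8% against 27.6 to 28.4% in the other 5 libraries, a gap of 1.79 percentage points. At an equal number of peaks the gap was 1.35, which argues against the number of peaks as the cause. Among peaks at or above the stricter score it was −0.305, since NG 1 stood lowest there (20.8%). SMG 3 (21.1%) still stood below the other libraries (21.7 to 22.9%). Among the weaker peaks the gap was 2.37, so it may lie mainly in the weak peaks of SMG 3. Its recovered background lay 0.0697% from that of SMG 1 and at least 8.41% from the others, and whether the word "normalized" marks sampling to a common depth cannot be told apart from a chance match, as the word is not explained. Simulated microgravity was not tested as an explanation, since SMG 1 and SMG 2 did not share the pattern.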

How the results depend on the processing

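Leaving out NG 1 and SMG 3 together was the alternative chosen only after the results were seen. Of 148 alternative values of the main results, 94 kept direction and call, where a count was kept if it stayed within 1.5 times. Another 36 moved, 16 reversed direction and 2 passed an adjusted p of 0.05 by Fisher's exact test where the main value did not. The 94 include differences with the replicate block, which equal the main ones by construction. With 3 libraries against 3 no exact test could pass 0.05, and the smallest exact p over the alternatives of the library measures was 0.2. Autosomes alone, an equal number of peaks and other overlap rules changed no direction and moved no count by over 1.5 times. The stricter score kept 15496 peaks of NG 1 and 20095 to 23113 of the other libraries, with an SMG minus NG difference of 1671 peaks. At that score the difference was −1.89 percentage points for the gene-end share and 0.343 for the intergenic share. The counts were 149 SMG-only regions, 47 NG-only regions and 7 NG-only genes. The cause was not tested. The 500 bp window gave −0.254 percentage points for the gene-end share, and the 3 kb window 2 lists without overlap. With all other union regions as background the odds ratios were 0.573 (SMG-only, gene end), 1.41 (SMG-only, within gene), 0.821 (NG-only, gene end) and 1.04 (NG-only, within gene). Without NG 1 and SMG 3 together the differences were −4.5 bp in width, −0.176 percentage points at gene ends and 0.168 between genes. That setting left 1153 SMG-only and 1216 NG-only regions, 75 SMG-only and 105 NG-only genes and 4 lists. Leaving out 1 library at a time gave −742 to 2223.5 peaks, −0.312 to 2.61 Mb, −3.83 to 26.2 bp, −0.305 to 0.346 percentage points at gene ends, 0.200 to 0.662 within genes and −1.19 to 0.0506 between genes. The Jaccard difference ran from −0.0102 to 0.0133. Counts rise by construction with fewer libraries to satisfy, to 421 to 859 SMG-only regions, 319 to 831 NG-only regions, 26 to 71 SMG-only genes, 33 to 70 NG-only genes and 0 to 3 lists. SMG-only regions were the more numerous in 5 of these 6 settings, and without NG 1 there were 421 against 831. In each setting the group that lost a library needed a peak in fewer libraries than the other, so the order of these counts is not on equal terms. The 24 named genes each lost the pattern at the stricter score. This was fixed in advance, since the weakest best peak of each lay at percentile 42.7 (LOC124902693) or lower, under that score. At an equal number of peaks 3 lost it, 8 with the 3 kb and 9 with the 500 bp window, and 0 reversed. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at −0.000515, 0.0195 and −0.0106. With the replicate block the differences were the same (716.333 peaks, 1.25464 Mb) with sign-flip exact p from 0.25, the smallest possible, to 1, and 0 lists were called. The motif test and its alternatives were not run, for want of a genome sequence, and the block gives no other count of regions by construction. Depth is known only through the recovered background, which limits any statement on weak peaks.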

Other observations

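The counts of regions per gene and the comparison of chromosomes were chosen only after the data were seen, and the test of gene length was set before its own result was seen. Genes of 3 T cell lists were the nearest genes of many regions held by all 6 libraries. T cell identity genes had a mean of 2.88 such regions within 50 kb, against 0.998 in random lists of genes of like length, leukaemic regulators 3.36 against 1.07, and activation genes 2.07 against 0.752. Each permutation p was 0.0002, two-sided, the smallest that 10000 random lists can give (adjusted p = 0.0014), so gene length does not account for the excess of T cell identity genes. Checkpoint and exhaustion receptors had 1.3 against 0.866 (permutation test, adjusted p = 0.318). The excess was not specific to T cell lists: of 28 lists tested, 14 stood above lists of like length at an adjusted permutation p under 0.05 and 1 below, and the identity, leukaemic and activation lists had the 3 highest ratios (2.75 to 3.15). Apoptosis genes had 2.04 against 0.903 (permutation test, adjusted p = 0.0014) and NF-kappaB genes 1.95 against 0.949 (adjusted p = 0.0028). Fibroblast markers had 0.231 against 1.01 (permutation test, adjusted p = 0.00684) and myeloid markers 0.308 against 0.773 (adjusted p = 0.102). RUNX1, a master regulator of blood cells, was the nearest gene of 9 such regions, ETS1 of 7, CD28, CD6 and LEF1 of 6 each and ZAP70 of 5. Outside the lists ANXA2R, FAT1 and ITPR1 each had 10 and IKZF1 had 8. These counts describe the cell line, in both groups alike, and genes are not independent replicates.

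The share of peaks on a chromosome was without overlap between groups for 5 of 24 chromosomes, where chance alone gives 10%. Chromosomes 9, 14 and 21 held more of the SMG peaks (3.72% ± 0.0761 against 3.61% ± 0.0424, 2.94% ± 0.0292 against 2.81% ± 0.0301, and 1.38% ± 0.0123 against 1.33% ± 0.00231; SD, n = 3 each, exact permutation p = 0.1, two-sided). Chromosomes 6 and 11 held less (5.77% ± 0.166 against 5.96% ± 0.0552, and 4.82% ± 0.0304 against 4.89% ± 0.0272; exact p = 0.1). The adjusted p was 0.48 for each of the 5 chromosomes, and another split of the 6 libraries, NG 1, NG 2 and SMG 2 against the rest, also parted 5 chromosomes.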
